A study of Mus musculus with 2 samples.

How the data were processed

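Per the labels' protocols, genomic DNA from frozen liver was cut with the enzymes TaqαI and MspI and ligated to methylated adapters. Fragments of 2 gel size ranges were bisulfite converted, amplified by PCR and sequenced on an Illumina HiSeq. There was 1 library from untreated and 1 from fasted mice, both of 12-week-old CD-1 mice, and the fast lasted 12 hr, per the labels' protocols. The submitters' processing notes name bcl2fastq 1.8.4, Bismark 0.14.3 and the build mm10. Alignment settings, read trimming, duplicate handling, the treatment of overlapping read mates and any filter on cytosines are not given in the sources used here.

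Each deposited file lists CpG cytosines by position and strand, with a text field giving methylated reads, total reads and the percent methylated, and a score column. The deposited score is 1000 times the methylated fraction, rounded, and it differed from the read counts by at most 0.5 in both libraries. The read counts in the text field were used for all values, so no normalization enters the levels. Start positions were converted to count from 1.

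The control library held 49253627 reads over cytosines and the fasted library 51276705, where a read counts once for each cytosine it covers. Cytosines with at least 10 reads in both libraries on the 19 autosomes were tested, strands kept apart. PCR reads without molecular identifiers are not independent molecules, so intervals and p-values cover counting error only. Intervals of shares are exact Clopper-Pearson intervals at 95%, and those of mean differences treat reads as independent draws at each cytosine.

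Samples were grouped by their titles, control and fasted. The coverage minimum, thresholds, windows of 1000 bp, gene lists, the tests that call cytosines, windows and genes, and most alternatives were fixed before the data were examined. Single cytosines were compared by a two-sided Fisher's exact test on methylated and unmethylated reads, with Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05 and a difference of at least 25 percentage points. Windows of 1000 bp with at least 3 cytosines and gene ends with at least 5 were called at an adjusted p under 0.05 of the same test on summed reads and a difference of at least 10 points between mean cytosine levels. Fisher's exact test on reads compares 2 libraries, and no spread between animals could be estimated. As a yardstick within a library, the 2 strands of the same CpG were compared by the same test.

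Gene positions came from a RefSeq gene table of assembly GRCm38.p6, the same build as mm10. The design defined promoters by the annotated start of transcription, but the table gives no strand, so that definition could not be applied. In its place, and chosen after the table was seen, a gene end window covered 1000 bp outside to 500 bp inside 1 end of the gene, taking the end with more shared cytosines. As a check of build and windows, 86.0% of protein-coding gene ends were below 10% methylated in the control library, against 36.8% of windows shifted by 100000 bp. Gene bodies ran from that window to the far end of the gene. Exons, introns, CpG islands and repeats were not analysed here, because they need a genome or gene models not used here.

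The named genes follow a rule fixed beforehand. They are the 10 protein-coding genes with the largest increase and the 10 with the largest decrease among called gene ends, each called member of a gene list, the 2 members of each list with the largest absolute difference, all measured imprinted genes, Xist and 10 fasting genes. The rule also names the 3 single cytosines and the 5 windows with the largest change in each direction. The 14 lists hold 405 symbols, of which 2 matched no gene. A list was described by the percentile of its median difference among 10000 random lists of the same size, drawn from 5 classes of methylation level. List calls were also adjusted over the list alone.

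Alternatives were other coverage minimums (5 and 20 reads), a cap on coverage, all chromosomes, equal depth by thinning reads, merged strands, read weighting, other thresholds, clustered cytosines, reads divided by the number of cytosines, other windows and other minimum numbers of cytosines. Added after seeing the data were the less methylated gene end, cytosines clustered at another CpG, and halving every read count. Halving was added because many read counts were even. It treats all reads as counted in pairs, which cytosines with 10 to 19 reads do not show, so it can remove too many. Differences of named genes under an alternative are printed where they turned or moved over 1.5 times and by at least 4 points, a rule chosen after seeing the data, and some smaller moves are printed too. The classes of methylation level in the profile, the comparison of neighbouring CpGs and the strand comparison at imprinted genes were also chosen after the data were seen. The tests were run on simulated data with known changes at 200 cytosines, windows or gene ends of each size. Gene ends changed by 10, 20 and 40 points were recovered in 31.5%, 83.5% and 100% of cases, and windows in 4.5%, 22% and 83.5%. Among items with no simulated change 0 cytosines, at most 2 windows and at most 3 gene ends were called. Such counts do not measure false calls in the real libraries, where some reads were counted in pairs and neighbouring cytosines share molecules. There, comparing the strands of 452020 CpGs within a library gave 279 calls in the control and 242 in the fasted library. The recovered shares likewise hold for the simulated changes only. Scripts used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.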

Results

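DNA methylation was measured in the liver of 12-week-old mice of the outbred CD-1 stock, either untreated or after 12 hr without food. The question named by the series title is how an overnight fast alters methylation across the liver genome. The assay was reduced representation bisulfite sequencing, which reads cytosines in fragments cut at CpG-rich restriction sites and reports an unmethylated cytosine as a converted base. There was 1 control library and 1 fasted library, and the labels did not say whether a library held 1 mouse or several. Every value below is therefore that of a single library with no replicate spread, and each test on reads compares those 2 libraries, not the conditions. Coordinates are in mm10.

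The control library listed 4111027 CpG cytosines with a median coverage of 8 reads, and the fasted library listed 4110421 with a median of 9. At least 10 reads covered 46.0% of the cytosines in the control library and 49% in the fasted library. Both strands of a CpG were listed as separate cytosines. On the autosomes 1603296 cytosines had at least 10 reads in both libraries, with a median coverage of 18 and 19 reads. Among cytosines of 20 to 80% methylation with 30 to 49 reads, both the methylated and the total read count were even at 57.8% in the control library and 54.3% in the fasted library, where independent reads would give about 25%. With 10 to 19 reads, the class of the median tested cytosine, the shares were 29.9% and 29.4%, so the excess was small there. Part of the reads were thus counted in pairs, and p-values and intervals, which cover counting error only, are too narrow.

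Average methylation of autosomal CpG cytosines was 35.4% in the control library and 35.5% in the fasted library, a difference of 0.0808 percentage points (0.067 to 0.0946, counting error). The mean difference per chromosome lay between -0.0756 and 0.252 points, and 16 of 19 autosomes were higher in the fasted library. Gene end windows stood at 8.61% in both libraries. Cytosines in gene bodies stood at 45.3% in both, and cytosines between genes at 68.0% in the control and 68.5% in the fasted library, a difference of 0.50 points (0.456 to 0.544). When each read rather than each cytosine was given equal weight, the autosomal levels were 28.5% and 29.4%, a difference of 0.859 points. Each library was then weighted by its own reads, so this value also holds shifts in where the reads fell. Within the classes of mean level below 10%, 10 to 80% and at least 80% the read-weighted differences were only 0.0413, 0.130 and 0.293 points. Much of the 0.859 points thus came from the share of reads in each class. On that weighting the difference was 0.0172 points between genes, 0.783 points in gene bodies and 0.521 points in gene end windows. Which of these differed most thus depended on the weighting. Across cytosines, which are not independent replicates, the levels of the 2 libraries correlated with a Pearson r of 0.969 and a Spearman rho of 0.899.

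Cytosines of different baseline levels moved in opposite directions. Cytosines with a mean level of 10 to 25% were lower in the fasted library by a mean of -1.18 points (95% bootstrap interval over blocks of 1000000 bp, -1.34 to -1.01), and those of 25 to 40% by -1.16 points (-1.43 to -0.890). Cytosines of 60 to 75% were higher by 0.886 points (0.728 to 1.04), and those of 75 to 90% by 0.787 points (0.703 to 0.866). On 19 of 19 autosomes the class of 10 to 25% was lower and the classes of 60 to 75% and of 75 to 90% were higher. Within gene bodies the class of 25 to 40% differed by -1.81 points, whereas between genes it differed by 0.0267 points. Simulated libraries with the same level at each cytosine gave -0.0149 points for the class of 10 to 25% and -0.0748 points for that of 60 to 75%. When the class was taken from 1 strand of a CpG and the difference from the other strand, the values were -1.12 points at 10 to 25% and 0.505 points at 60 to 75%. These classes were chosen after the data were seen, and at cytosines with at least 50 reads the differences were -0.565 points at 10 to 25% and 0.0236 points at 60 to 75%.

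**Figure D1:**
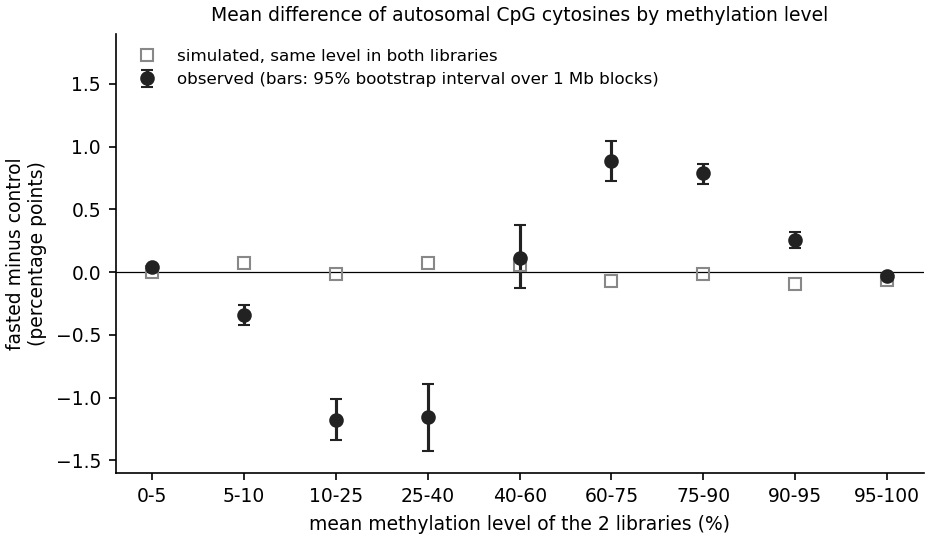
Mean difference in methylation (fasted minus control library, percentage points) of autosomal CpG cytosines with fewer than 1000 reads, by the mean level of the 2 libraries (%); filled points are observed means with 95% bootstrap intervals over blocks of 1000000 bp, and open squares are simulated libraries with no change. The classes of 10 to 25% and 25 to 40% lie at -1.18 and -1.16 points, and those of 60 to 75% and 75 to 90% at 0.886 and 0.787 points.

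Single CpG cytosines with the largest changes switched from no methylation to full methylation or the reverse. A cytosine inside Cacna1a, which encodes a P/Q-type calcium channel subunit, went from 0% of 28 reads to 100% of 45 reads (chromosome 8, position 84569303). A cytosine inside Arhgap26 went from 0% of 22 to 100% of 46 reads (chromosome 18, position 39114292), and one lying 4263 bp from Cbln4 went from 0% of 32 to 100% of 28 reads (chromosome 2, position 172047729). Cytosines inside Gm35341 (chromosome 1, position 186412094) and inside Pkd2l1 (chromosome 19, position 44149577) went from 100% of 37 and of 32 reads to 0% of 30 and of 33 reads. A cytosine 59742 bp from Rarb, a retinoic acid receptor gene, went from 100% of 32 to 0% of 28 reads (chromosome 14, position 17142073). Whether these positions lie in exons or introns was not analysed here.

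In all, 1315 of 1603296 autosomal cytosines (0.0820%) passed a two-sided Fisher's exact test with Benjamini-Hochberg adjustment and a difference of at least 25 points. Of these, 719 were higher and 596 were lower in the fasted library. Cytosines between genes held 175 calls per 100000 tested, gene bodies 87.2, and gene end windows 32.4. This order in part follows baseline levels, since cytosines with a mean level below 10% could not differ by 25 points and held 0 calls. In the control library 11.7% of cytosines between genes, 40.3% in gene bodies and 86.7% in gene end windows were below 10% methylated. The strand partner of a called cytosine, the other cytosine of the same CpG, showed a median of 0.780 of its difference (749 pairs), and the nearest other CpG within 50 bp showed a median of 0.0777 (1170 pairs). Within a library, comparing the 2 strands of 452020 CpGs in the same way gave 279 calls in the control and 242 in the fasted library, against 393 and 381 calls between the libraries on the plus and the minus strand. On simulated changes centred on 50% the test recovered 99% of changes of 100 points, 55% of 75 points, 2% of 50 points and 0% of 25 points, so most changes of that kind up to 50 points would have been missed at this depth. With every read count halved, 47 cytosines were higher and 39 lower.

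**Figure D2:**
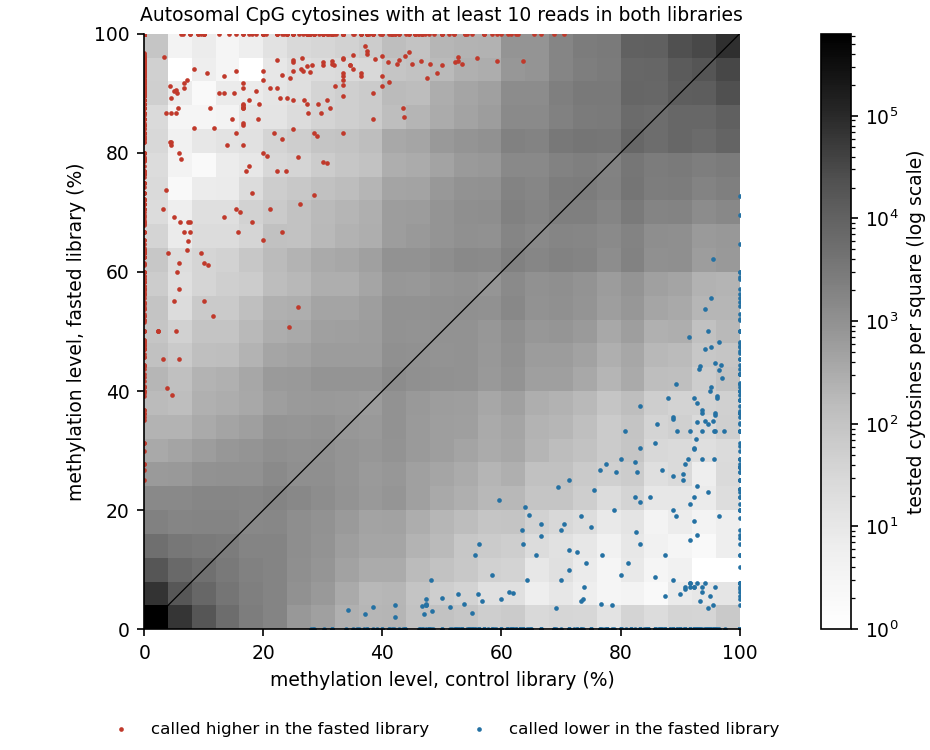
Methylation level (%) of 1603296 autosomal CpG cytosines in the control library (horizontal axis) and the fasted library (vertical axis); grey squares give the number of cytosines on a log scale, and dots are the 719 cytosines called higher (red) and the 596 called lower (blue). Called cytosines lie near the edges of the plot, mostly near 0% or 100% in at least 1 library.

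Among windows of 1000 bp, the largest decrease was from 95.5% to 0% over 4 cytosines on chromosome 5 (3235001 to 3236000), 105004 bp from Cdk6, a cell cycle kinase gene. A window inside Gm3786 fell from 96.3% to 13.4%, with all 18 cytosines lower (chromosome 5, 117294001 to 117295000). Windows inside Rhbdf1, an inactive rhomboid gene, inside Cyp2c23, a cytochrome P450 of arachidonic acid metabolism, and inside Med12l fell from 94.6% to 21.8%, from 91.1% to 25.9% and from 94.7% to 33.3%. The largest increase was from 0% to 93.9% over 3 cytosines on chromosome 6 (140385001 to 140386000), 37639 bp from Plekha5. A window on chromosome 17 (40372001 to 40373000), 52794 bp from Crisp1, rose from 21% to 89.6%, with all 13 cytosines higher. Windows 5 bp from Slc6a21, 4 bp from Gm8773 and inside Ptprg, a receptor tyrosine phosphatase gene, rose from 15.2% to 87.0%, from 12.5% to 83.0% and from 35.9% to 97.9%.

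Of 124884 windows, 1326 were called higher and 1176 lower, and 34 of the calls reached 50 points. The call required a difference of at least 10 points and a Fisher's exact test on summed reads, with Benjamini-Hochberg adjustment. Neighbouring cytosines share molecules, and with the reads divided by the number of cytosines 5 windows were called higher and 2 lower. With every read count halved 164 were higher and 162 lower.

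Among called ends of protein-coding genes, the largest increase was at Gm8773, from 15.1% to 86.3% (adjusted p = 1.01e-58, Fisher's exact test). All 11 of its cytosines were higher (chromosome 5, 5573004 to 5574503). From summed reads its level was 11.4% in the control library (95% exact interval 7.59 to 16.3) and 85.7% in the fasted library (80.4 to 90). Reads were summed over neighbouring cytosines that share molecules, so these intervals are too narrow and the p-value too small. Eng, the TGF-beta co-receptor endoglin of endothelial cells, rose from 32.7% to 67.0%, and Gpihbp1, which anchors lipoprotein lipase to capillary endothelium, rose from 33.2% to 61.1%. Aebp2, a cofactor of the Polycomb complex PRC2, rose from 45.5% to 73.2%, and Tlk2, a kinase of chromatin assembly, from 60.1% to 88.4%. Erich3 rose from 36.3% to 73.3%, Egfem1 from 16.3% to 46.9%, and Cd55b, a complement regulator gene, from 53.1% to 83.2%. Dnajb3 rose from 42.7% to 73.6% and Dkkl1 from 24.1% to 50.1%, both genes known for expression in testis.

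The largest decrease among called ends of protein-coding genes was at Tescl, from 53.1% to 10.9%. All 26 of its cytosines were lower (chromosome 7, 24332080 to 24333579). BC029722 fell from 40.4% to 0.707%, also with all 26 cytosines lower (chromosome 2, 155818733 to 155820232; adjusted p = 1.81e-131, Fisher's exact test). From summed reads its level was 41.3% in the control library (38.0 to 44.7) and 0.799% in the fasted library (0.366 to 1.51). Each of its cytosines held 15 to 46 reads in the control library. Neighbouring cytosines share molecules, so here too the intervals are too narrow and the p-value too small. Snrnp25, a protein of the minor spliceosome, fell from 85.6% to 47.9%, and Akr1b8, an aldo-keto reductase, from 55.5% to 18.2%. Eddm3b fell from 55.2% to 21.2% and Arl9, a small GTPase gene, from 90.4% to 56.8%. The overlapping windows of Tpsg1, a mast cell tryptase, and Cacna1h, a T-type calcium channel, fell from 56.5% to 27.7% and from 58.5% to 30.9%. Cd37, a tetraspanin of B cells, fell from 53.2% to 27.3%, and Krt8, a keratin of hepatocytes and other epithelia, from 30.7% to 5.32%.

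**Figure D3:**
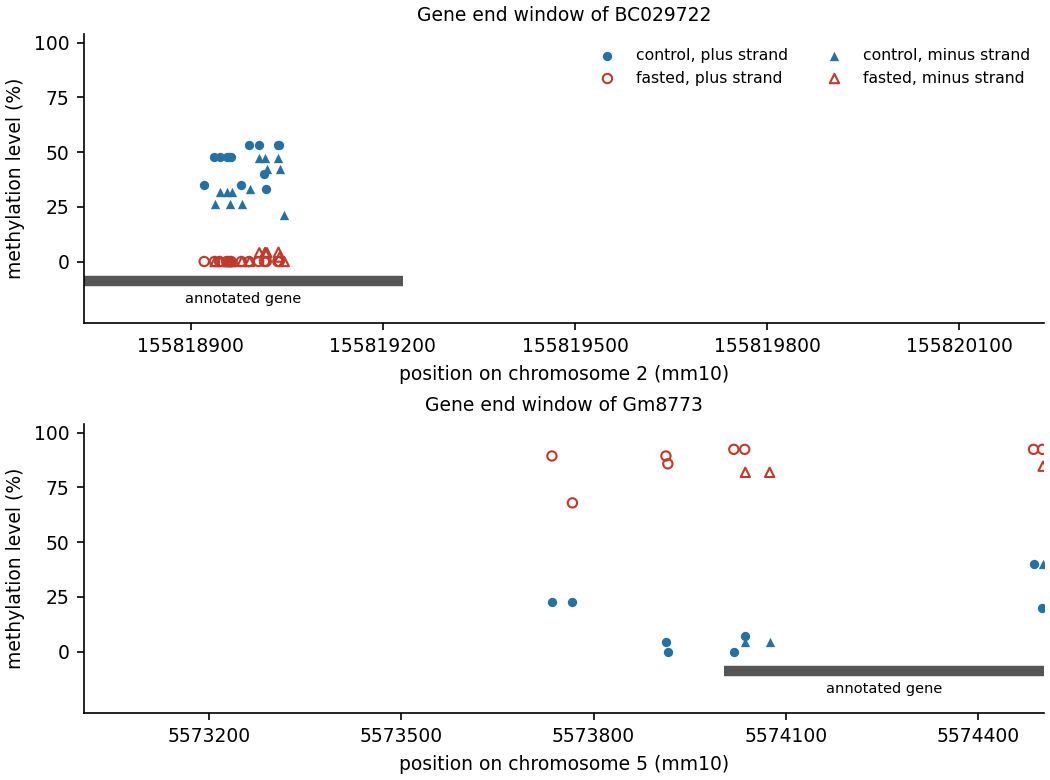
Methylation level (%) of each cytosine with at least 10 reads in both libraries across the gene end windows of BC029722 and Gm8773 (mm10 position on the horizontal axis); filled blue symbols are the control library, open red symbols the fasted library, circles the plus and triangles the minus strand, and the grey bar the annotated gene. In BC029722 all 26 cytosines were lower in the fasted library, and in Gm8773 all 11 were higher.

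Of 17378 measured gene ends, 131 were called higher and 133 lower in the fasted library, in 253 distinct windows. Among 12259 protein-coding genes, 59 were called higher and 48 lower, and 90.1% of all measured gene ends differed by less than 5 points. With reads divided by the number of cytosines 1 gene end was called higher and 2 lower, with Gm8773 and BC029722 the 2 named genes among them. With every read count halved 27 gene ends were higher and 31 lower, and the calls of Cd55b, Tlk2, Gpihbp1, Aebp2, Eddm3b, Cd37 and Krt8 were lost. With windows of 2000 bp on each side Egfem1, Aebp2 and Krt8 lost their calls as well, with differences of 2.52, 2.92 and -5.44 points, and the difference was -16.3 points for Tlk2, 1.05 points for Cacna1h and 0.574 points for Cd37, against the direction given above. With the same windows Gm8773 differed by 47.2, Gpihbp1 by 13.0 and Akr1b8 by -23.2 points, and with a minimum of 5 reads Tlk2 differed by 16.9 and Krt8 by -12.9 points. At the less methylated gene end Snrnp25 differed by -1.69 points and was not called. Gene bodies averaged 48.2% in the control and 48.1% in the fasted library over 12122 genes.

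Measured ends of genes of the fasting response ranged from 0.430% at Ppara to 15.9% at Pck1. The gene table gave no strand, so the measured end of a gene, here and in the lists below, may be its start or its far end. These values are therefore not promoter values as such, and at Pck1 the end with the higher coordinate was measured. Pck1, the cytosolic enzyme that starts gluconeogenesis from oxaloacetate, stood at 15.9% in the control and 14.8% in the fasted library, and with a minimum of 5 reads it differed by 8.53 points. Ppargc1a, a transcriptional coactivator of gluconeogenesis, stood at 1.16% and 2.32%, and Cpt1a, which carries fatty acids into mitochondria, at 7.16% and 5.64%. Ppara, the nuclear receptor of fatty acid oxidation, stood at 1.24% and 0.430%, and Fasn, the fatty acid synthase, at 0.506% and 0.635%. None of these 5 passed the test, with adjusted p between 0.379 for Ppargc1a and 1 for Pck1 in Fisher's exact test. With a minimum of 20 reads the differences were -0.0182 points at Ppargc1a and 0.635 points at Fasn, and with windows of 2000 bp Ppargc1a differed by 0.227 points. G6pc, Srebf1 and Igfbp1 had 0 shared cytosines at either end and Fgf21 had 1, so these 4 were not measured.

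Of 13 measured genes of gluconeogenesis, 1 was called higher, Gpi1, whose product interconverts glucose and fructose phosphates. It rose from 7.85% to 23.2% with 17 of 34 cytosines higher and 3 lower (adjusted p = 2.00e-44, Fisher's exact test). It was also the 1 call of this list when adjusted over the list alone. The Gpi1 call was lost with reads divided by the number of cytosines and with a required difference of 20 points. Gpt, an alanine transaminase, stood at 65.3% and 50.4% without passing the test, and differed by -2.96 points with windows of 2000 bp. Among 28 genes of glucagon, insulin and cAMP signalling 0 were called, with Akt1 at 8.05% and 3.73% and Hnf4a, a hepatocyte transcription factor, at 33.0% and 29.4%. Among 21 genes of fatty acid oxidation, ketogenesis and PPARA targets 0 were called. Pdk4, a kinase that shuts pyruvate dehydrogenase, stood at 0.620% and 5.84% (adjusted p = 0.00660, Fisher's exact test), a difference below the required 10 points, and Pnpla2, the adipose triglyceride lipase, at 29.3% and 31.1%, with a difference of -2.48 points at a minimum of 5 reads. The median difference of this list, 0.235 points, lay at percentile 93.8 of random lists, and at 46.7 with a minimum of 5 reads.

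Lipogenesis and glycolysis had 0 calls in 21 genes, with Gpam, which starts glycerolipid synthesis, at 7.77% and 20.4% and Acacb, an acetyl-CoA carboxylase, at 9.70% and 11.7%. Cholesterol and bile acid metabolism had 0 calls in 18 genes. Its members with the widest gaps were Scarb1, the HDL receptor, at 24.1% and 14.9% (called at equal depth, -10.5 points), and Nr0b2, a repressor of bile acid synthesis, at 21% and 13%. Amino acid catabolism and the urea cycle had 0 calls in 19 genes, with Sds, a serine dehydratase, at 17.8% and 12.9% and Arg1, the arginase of the urea cycle, at 2.43% and 7.14%. Autophagy and lysosome genes had 0 calls in 23, with Lipa, the lysosomal acid lipase, at 4.31% and 0.833% and Gabarap at 0% and 1.03%. Circadian clock genes had 0 calls in 18, with Nfil3 at 4.35% and 0.417% and Csnk1e at 14.6% and 12.1%. DNA methylation and one-carbon genes had 0 calls in 25, with Gnmt, which consumes S-adenosylmethionine, at 6.44% and 10.3% and Tet1, a methylcytosine dioxygenase, at 2.74% and 6.46%. Adjusted over the list alone, these 6 lists also had 0 calls, as did the signalling and the fatty acid oxidation lists. Mean levels of all these lists in the control library ran from 0.702% for autophagy to 6.12% for cholesterol, and an end at such a level could not fall by the required 10 points. Of all measured gene ends 1.52% were called, so 0 calls in lists of this size do not show a lack of change. With a minimum of 5 reads Acacb, Arg1, Gnmt and Nfil3 turned to -3.56, -0.504, -0.423 and 0.792 points. With windows of 2000 bp Nfil3 and Tet1 turned to 0.316 and -0.967 points, and at a minimum of 20 reads Tet1 differed by 1.04 points.

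Imprinted genes, which carry methylation on 1 parental allele, averaged 32.6% in the control and 32.7% in the fasted library over 24 gene ends. Of these, 3 were called higher and 3 lower, and 8 passed when adjusted over the list alone. Zrsr1 rose from 20.5% to 35.7%, Mest from 50% to 63.4% and Peg13 from 40% to 52.1%. Ndn fell from 31.1% to 9.14%, Meg3 from 51.5% to 37.6% and H19 from 37.9% to 26.7%. The calls of Zrsr1, Mest, Peg13, Ndn, Meg3 and H19 were lost with every read count halved. With at least 20 reads per cytosine the difference of Zrsr1 was -2.61 points, and Meg3 was no longer called. With a minimum of 5 reads Peg13 and H19 differed by 6.62 and -3.17 points and were not called. At equal depth Meg3 and Peg13 lost their calls, and with windows of 2000 bp Ndn, Zrsr1 and Peg13 lost theirs, with differences of -11.7, 6.42 and 7.71 points. The 2 strands of the Mest window differed by 0.253 and 31.6 points.

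Other imprinted ends were not called over all gene ends, though Nap1l5 and Peg3 passed when adjusted over the list alone. With a minimum of 5 reads Magel2 (-10.1 points) and Igf2r (10.8 points) were called, and Nap1l5, Cdkn1c, Nnat and Peg12 differed by -4.26, 2.36, -7.13 and -7.26 points. With a minimum of 20 reads Magel2, Gnas, Nnat and Usp29 differed by -2.96, 1.25, 6.50 and 12.4 points. With windows of 2000 bp the differences were -5.96 points at Gnas, -0.354 at Cdkn1c, -9.20 at Peg12 and -0.472 at Rasgrf1. Nap1l5 stood at 85.9% and 72.2%, Peg3 at 34.7% and 46.7%, Usp29, whose window overlaps that of Peg3, at 32.5% and 40.6%, Cdkn1c at 32.5% and 42.1%, Magel2 at 24.7% and 15.2%, and Gnas at 29.1% and 37.2%. Plagl1 stood at 35.6% and 30.7%, Mcts2 at 34.7% and 39.2%, Zdbf2 at 89.5% and 85.8%, and Peg12 at 12.4% and 9.12%. Smaller gaps were seen at Igf2r (23.1% and 25%), Nnat (53.1% and 54.9%), Zim1 (1.65% and 0%), Rasgrf1 (3.26% and 1.77%) and Airn (28.7% and 29.7%). The levels of Inpp5f (0.202% and 0.601%), Mkrn3 (24.8% and 24.6%) and Grb10 (4.41% and 4.25%) differed by less than 0.5 points.

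Marker genes of liver cell types were read the same way. Of 13 endothelial, stellate and cholangiocyte markers 2 were called higher, Eng and the stellate cell gene Pdgfrb, which rose from 25.9% to 50.7%. The call of Pdgfrb was lost with every read count halved. The list median was -0.271 points, 9 of 13 members were lower, and 2 calls were made when adjusted over the list alone. Of 10 hepatocyte markers 0 were called, with Fga at 28.4% and 37.7% and Ambp at 15.5% and 24.3%. Of 5 immune cell markers 0 were called, all 5 with higher values in the fasted library, among them Itgal at 69.9% and 82.8% and Clec4f, a Kupffer cell gene, at 77.3% and 80.4%. With levels from summed reads Itgal differed by 8.54 and Clec4f by 8.93 points, with a minimum of 5 reads Clec4f by 7.84 points, and with windows of 2000 bp Fga by 3.20 points. Of 4 sex-biased liver genes 0 were called, with Moxd1 at 5.72% and 4.57% and Cux2 at 0.712% and 1.32%. Moxd1 differed by 0.186 points when levels were taken from summed reads, and Cux2 by -0.0687 points with windows of 2000 bp. Adjusted over the list alone, the hepatocyte, immune and sex-biased lists had 0 calls. With 1.52% of all measured gene ends called, 0 calls in so few genes do not show a lack of change. None of the 14 list medians lay outside the middle 95% of 10000 random lists of the same size matched on methylation level, with percentiles from 12.2 for gluconeogenesis to 93.8. With a minimum of 5 reads gluconeogenesis lay at percentile 73.5.

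**Figure D4:**
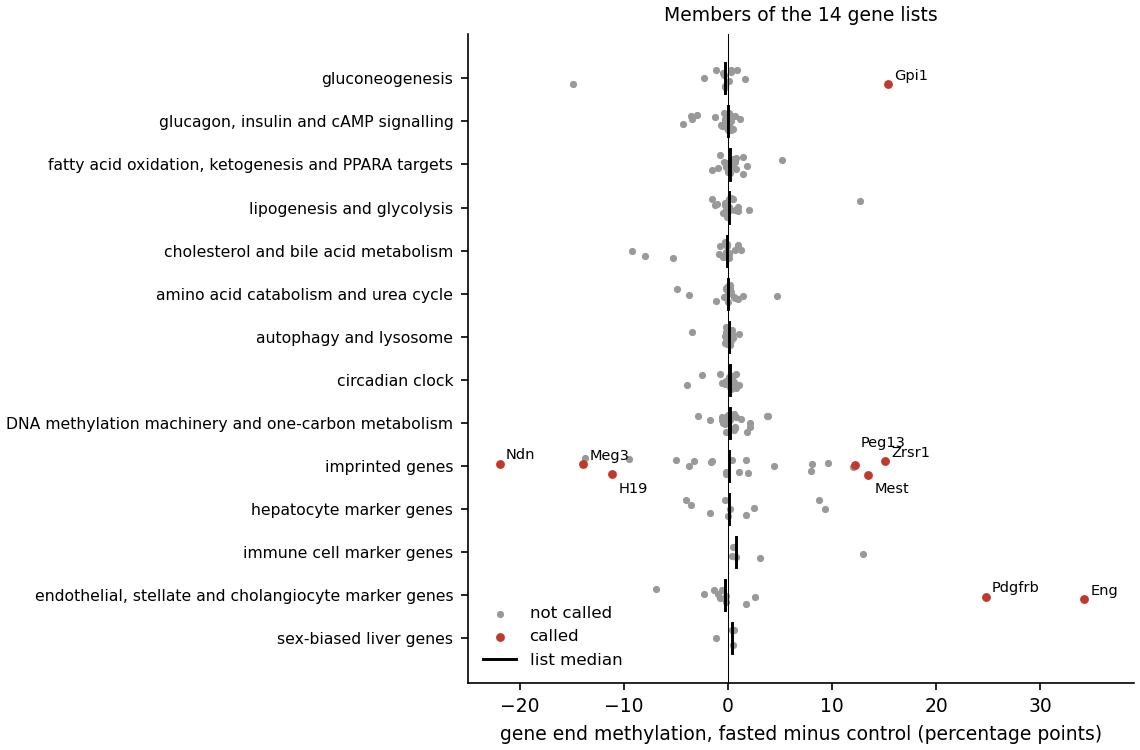
Difference in gene end methylation (fasted minus control library, percentage points) of each measured member of the 14 gene lists; red dots are called genes, grey dots genes not called, and black bars list medians, with vertical scatter for legibility. The called genes are Gpi1, Zrsr1, Mest, Peg13, Eng and Pdgfrb above 0 and Ndn, Meg3 and H19 below 0.

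The X chromosome averaged 39.3% in the control and 39.4% in the fasted library, and the Y chromosome 76.1% and 76.7%. Both libraries held Y-chromosomal reads, 77529 in the control and 69392 in the fasted library. Mean coverage of X cytosines was 0.483 of the autosomal mean in the control and 0.472 in the fasted library. Xist, the RNA that silences an X chromosome in females, had 0 shared cytosines in its end windows, and over the gene and 1000 bp on each side its level from reads was 96.7% and 95.9%. Mitochondrial cytosines read as methylated made up 0.948% of reads in the control library (exact interval 0.872 to 1.03) and 0.898% in the fasted library (0.823 to 0.978). Unplaced scaffolds averaged 63.8% and 63.6%.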

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

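The tests on called cytosines and on mitochondrial reads were chosen only after the result was seen, and the other tests were set out before their values were computed but after the patterns had been seen. At imprinted genes the test replaced 2 earlier ones after their values were known, and a later test of a shift in 1 direction was dropped, since the pattern itself fixed its outcome.

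A signal outside the shared cytosines was present in 3490 autosomal cytosines with at least 20 reads in the fasted library and none in the control library, in 1265 stretches with gaps of up to 300 bp. The reverse held for 3179 cytosines in 1105 stretches, and neither was compared by a test.

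Called single CpG cytosines formed the first pattern. Random error within a library is argued against for most calls with a measured strand partner, which showed a median of 0.780 of the difference of the called cytosine (bootstrap interval 0.738 to 0.833). In 69.6% of 749 pairs the partner moved at least 0.5 times as far. Such error stays open for the other calls, since comparing strands within a library gave 279 and 242 calls, against 393 and 381 between the libraries. A methylation change over the surrounding region does not account for most calls, since the nearest other CpG within 50 bp moved at least 0.5 times as far in the same direction in 18.6% of 1011 pairs whose neighbour had a level of at least 50% where the called cytosine was high (19.9% of all 1170 pairs). A sequence variant at the CpG itself in this outbred stock may underlie many calls, since the neighbour in those 1011 pairs showed a median of 0.0714 of the difference (0.0485 to 0.0890), and in all 1170 pairs 0.0777 (0.0583 to 0.0938). A methylation change limited to 1 CpG would give the same values, so it stays open, as do fasting and other differences between the mice.

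The second pattern was a region of very high coverage on chromosome 17 (39840342 to 39848710), which holds Rn18s-rs5, a gene related to 18S ribosomal RNA. Over 786 cytosines its mean level was 17.7% in the control and 21% in the fasted library, with 641 cytosines higher and 142 lower. Incomplete bisulfite conversion in the fasted library is argued against by mitochondrial reads, which differed by -0.0498 points (-0.159 to 0.0593). A shift of all cytosines of that level is argued against too, since other cytosines of 10 to 25% differed by -1.19 points (-1.29 to -1.08). That comparison held only cytosines with fewer than 1000 reads in each library. Of 8 other loci with at least 1000 reads and a mean level below 30%, 7 were higher in the fasted library and 1 was lower. A rise shared by loci of very high coverage and low level thus stays open. Fasting, a difference between individual mice and a different mix of repeat copies stay open and were not tested.

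The third pattern was the differences at imprinted gene ends in both directions. Across 22 imprinted ends with at least 2 cytosines on each strand, the differences on the plus and the minus strand correlated with a Pearson r of 0.287 (bootstrap interval -0.0277 to 0.669), just under the 0.3 set out for random error within a library, and a Spearman rho of 0.361. Such error may thus account for part of the differences, with 13 of 22 ends of the same sign on both strands, and the wide interval leaves a shared change open. Fasting and other differences between the mice stay open as untested.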

How the results depend on the processing

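The less methylated gene end, clustering at another CpG and halved read counts were chosen only after the result was seen. Across alternatives 43 summary values were classed as the same and 38 as moved, and all 56 list percentiles stayed inside the middle 95%. A count was classed as the same within a factor of 1.5, and the mean difference within its counting error interval. Apart from the read weighting described above, the cause of each move was not tested, except where fewer cytosines, fewer reads or a stricter threshold brings it by construction. The mean difference stayed positive throughout. The larger of the counts higher and lower changed sides for cytosines clustered at another CpG, for windows at a minimum of 20 reads and for gene ends at 20 points, with levels from summed reads, with windows of 2000 bp and at the less methylated end. A minimum of 20 reads, equal depth and halved counts each left fewer calls of every kind.

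The mean difference was 0.14 points at a coverage minimum of 5, 0.0177 at 20 and 0.120 with strands merged. It was 0.859 with reads weighted equally, which also reflects where the reads of each library fell. Cytosines higher and lower numbered 417 and 361 at a minimum of 20 reads, 445 and 347 at equal depth, 1307 and 1082 with strands merged, 469 and 357 at an adjusted p under 0.01, 251 and 186 when clustered, 95 and 102 when clustered at another CpG, and 47 and 39 with halved counts. Windows of 1000 bp higher and lower numbered 443 and 452 at a minimum of 20 reads, 827 and 770 at equal depth, 735 and 633 at 20 points, 164 and 162 with halved counts, and 5 and 2 with reads divided by the number of cytosines. Gene ends higher and lower numbered 37 and 50 at a minimum of 20 reads, 45 and 41 at 20 points, 71 and 76 with at least 10 cytosines, 27 and 31 with halved counts, and 1 and 2 with reads divided by the number of cytosines.

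Of 28 called named gene ends, 6 (Gm8773, BC029722, Tescl, Arl9, Tpsg1 and Dkkl1) stayed measured and called under all alternatives but reads divided by the number of cytosines, which kept 2 named calls. At halved counts 14 of the 28 stayed called. With at least 10 cytosines 13 of them had too few cytosines for a value. The difference reversed at Zrsr1 with a minimum of 20 reads (-2.61 points), and with windows of 2000 bp at Tlk2 (-16.3), Cacna1h (1.05) and Cd37 (0.574). Of 46 named gene ends not called, 40 turned sign or moved over 1.5 times under at least 1 alternative, and 19 turned sign. The cause was not tested.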

Other observations

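The values here were all looked at only after the data were seen, with no test planned. Beside the region of Rn18s-rs5, 14 other loci of 10000 bp held cytosines with at least 1000 reads in both libraries. Of the 8 with a mean level below 30%, 7 were higher in the fasted library, and of the 6 with a mean level of at least 30%, 5 were lower. The differences ran from -1.89 to 4.19 points in the former and from -14.4 to 0.909 points in the latter. The loci at these extremes each held only 1 or 2 such cytosines.

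Among 904 called cytosines with at least 80% methylation in the higher library, the ratio of the lower to the higher level was under 0.1 at 482 cytosines, from 0.1 to 0.2 at 51, from 0.2 to 0.3 at 103, from 0.3 to 0.4 at 124 and from 0.4 to 0.5 at 83. Of 16 imprinted ends with a mean level of 20 to 70%, 6 were called (37.5%), against 131 of 1304 other gene ends in that range (10%). The median absolute difference was 8.84 points at the imprinted and 5.51 points at the other ends.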
